A study of Oryza sativa with 2 samples.

How the data were processed

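Rice (Oryza sativa) seedlings exposed to jasmonic acid, a plant hormone made on wounding and attack, were set against unexposed seedlings on 2 two-colour oligonucleotide arrays. The labels give a dose of 5 µM, an age of 7 days and a total RNA source. They disagree on 2 points: the sample titles name shoots where the design text speaks of whole seedlings, and the treated channel is described as exposed for 7 days where the design text has seedlings of that age exposed. On array 1 the control RNA carried Cy3 and the treated RNA Cy5, and on array 2 the dyes were exchanged. Both arrays carry the same replicate number in the labels, so they were counted as a technical dye swap and 1 replicate. No p-value across genes was computed, and no spread between plants could be measured.

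The deposited values are 1 log10 ratio per spot and array, for 22575 spots with no missing value. Per the labels, a GenePix scanner and its software gave the images and spot values, and GeneSpring version 4 was used for normalization. Background correction and filters are not given in the sources used here. The deposited log10 ratios are not centred: their medians are −0.0902 on array 1 and −0.0954 on array 2. Taken to the power of 10, the values are ratios of whole numbers, with no trace of a factor per array. Whether the numerator is a dye or an RNA is not stated, so scale is known, centring is absent and direction stays unknown. All values below were multiplied to the log2 scale.

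The whole-number ratio behind each value was recovered as the simplest fraction within 6e-10 on the log10 scale. The log2 geometric mean of its reduced terms, averaged over the arrays, served as a measure of spot brightness. Common factors cancel in a reduced fraction, so this is a lower bound on signal. Spots with a log2 ratio below −2.2 on both arrays and a brightness above 4.5 were called control-like, and there were 228. The thresholds were set after seeing the values.

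The annotation table given with the series lists 17860 of the 22575 features, of which 17839 have 1 gene, 21 have several and 4715 have none. No name was taken from a feature with several genes. All 17839 matched a gene number in the RefSeq table of assembly ASM3414082v1, which was used for names and gene order only. They belong to 15798 genes, and 2093 of these have a name other than a locus or clone number. A gene with several probes took their mean on each array; in 777 of the 1859 such genes the swap means of the probes differed in sign.

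The spot numbers, taken as they stand, did not pair with the annotation. With them, 85.1% of the control-like spots fell on features with a gene, against 79.1% of all features, and 1690 pairs of probes for 1 gene showed a Spearman correlation of 0.01 in their swap mean (defined below). Rearrangements of the spot grid were therefore searched, after the values had been seen: 98 grids, with every line length that divides the number of spots and leaves no side under 15, transposed or not and turned in either axis, and 400 shifts of the numbers. A grid of 215 lines of 105 spots, transposed and turned in both axes, put 0 of the 228 control-like spots on a feature with a gene; the lowest share among the others was 69.3%. The same grid gave a pair correlation of 0.30, against at most 0.11 in absolute value among the others and 0.08 over 1000 shuffles of the pairs. Over 442 pairs with both probes above the median brightness it was 0.52. Every gene name and list below rests on this grid, which no source states. It was picked by its share of control-like spots on features with a gene, before gene values were seen under it. The pair correlation was computed beside this share and did not enter the choice. The decision to print names through the grid was written down after gene values had been seen.

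The direction rule, fixed before the data were examined, read a positive correlation of the columns as treated over control on both arrays and a correlation below −0.3 as 1 dye over the other. Over all probes the correlation was 0.54, which the rule would read as treated over control, called likely. That reading was set aside after the values had been seen, because the correlation was negative among the brightest probes. The rule gives no direction where the files contradict both readings, and the values were taken as such a case. Sizes are therefore given without a direction. The deposited values are reported as planned, with their plain mean over the arrays. The swap mean, the mean of array 1 and of array 2 with its sign turned, is given beside it. A probe is on the array 1 side when its ratio is at least 2-fold above 1 on array 1 and at least 2-fold below 1 on array 2, and on the array 2 side in the opposite case. If the numerator is Cy5 on both arrays, which is the usual form for such scanners and is not stated, the array 1 side is higher in treated seedlings; if it is Cy3, it is lower there. If the columns are instead treated over control, the swap mean holds dye effects of probes and no effect of the treatment, and the plain mean holds the latter.

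Counts of probes past 2-fold on both arrays were set beside the number expected if the arrays were independent. For 30 gene lists the median over genes was placed among 10000 random lists of the same size, unmatched because the files hold no intensity, and also matched on brightness in 20 bins. Percentiles for an array alone were taken among unmatched lists only. The lists were first fixed by words in gene descriptions. The tables hold symbols and synonyms only, so the same lists were rewritten as symbol patterns after the files were opened and before any gene value was seen; their medians were also looked at once under the spot numbers as they stand. The named genes are, among genes with a name and past 2-fold on both arrays in the same direction, the 12 with the highest and the 12 with the lowest mean, and per list the 3 members with the largest absolute mean. The rule was written for the plain mean and was applied to the swap mean as well.

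Alternatives were centring and scaling, 1.5-fold and 3-fold thresholds, the mean alone, each array alone, genes in place of probes, leaving out the dimmest spots or the control-like spots, turning array 2, other rules for several probes, matching on brightness and names by spot number. A list counted as turned round when it lay outside the central 95% of random lists and crossed to the other side of their middle. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The steps were tested on simulated data over 22575 spots: the placement of the grid was recovered, and of 200 changed spots 99% of those changed by 3-fold and 100% of those changed by 6-fold were found, with 0 unchanged spots called. The simulated noise had 1 size at every spot and no offset at dim spots, and changes had opposite signs on the arrays. Simulated control spots were placed on features without a gene. The test therefore covers the working of the steps and not the error of these arrays. The number of arrays limits the precision.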

Results

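Two-colour arrays compared RNA of 7-day-old rice seedlings exposed to 5 µM jasmonic acid with RNA of unexposed seedlings, on 2 arrays with exchanged dyes that count as 1 replicate. Each array gave 22575 log ratios, with a median of −0.30 (log2) on array 1 and −0.32 on array 2 and a spread (scaled median absolute deviation) of 0.37 and 0.40. The median spot brightness was 4.83 (log2) on array 1 and 5.99 on array 2. There was no biological replicate, so every value below describes these arrays only. Gene names rest on a rearrangement of the spot grid found from the data, since the spot numbers as deposited did not pair with the annotation.

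The first comparison asked whether the deposited ratios of the exchanged arrays go together. Over all 22575 probes Pearson's r was 0.54 and Spearman's rho 0.42, across probes, which are not independent replicates. The correlation depended on brightness: Pearson's r was 0.58 in the dimmest of 10 equal groups of probes and −0.72 in the brightest, where Spearman's rho was −0.50. Pearson's r was above 0 in the other 8 groups, for instance 0.57 in the eighth; without the control-like spots it was −0.08 in the fifth, −0.48 in the eighth and −0.55 in the ninth. In the dimmest group the median was −1 on each array, and 1967 of its 2258 probes had ratios below 1 on both. In the brightest of 4 groups, without control-like spots, 67 of the 79 probes at least 2-fold higher on array 1 were at least 2-fold lower on array 2. Of the 50 at least 2-fold lower on array 1, 21 were at least 2-fold higher on array 2 and 5 were lower on both. The deposited ratios therefore carry no settled direction, and gene values are given as sizes on the array 1 side or the array 2 side. Every swap mean below changes sign if the numerator is the other dye. If the columns are treated over control, swap means and sides measure dye effects of probes and not the treatment.

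**Figure D1:**
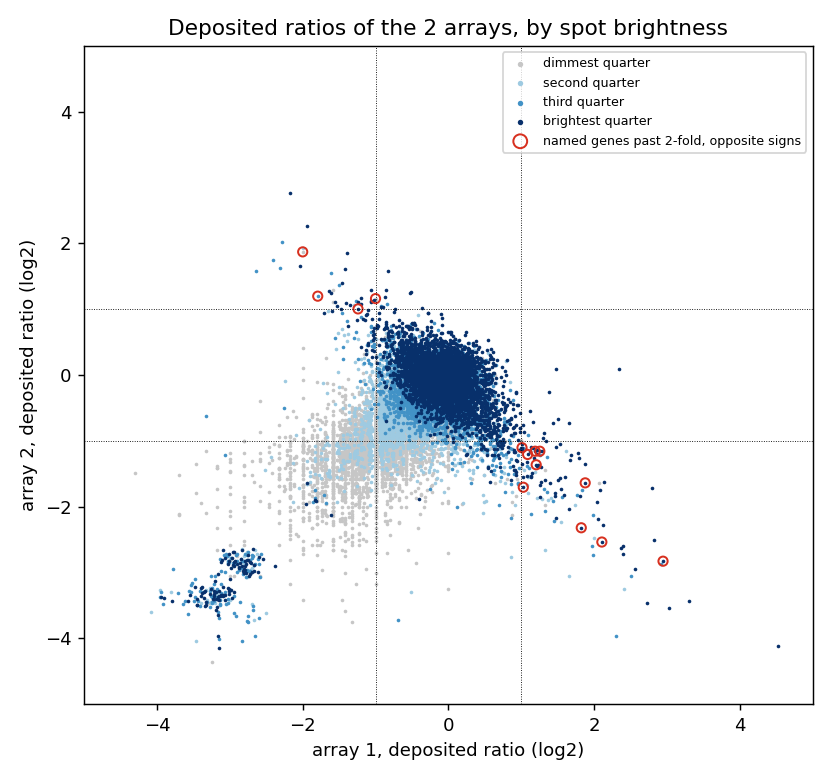
Deposited log2 ratios of each of the 22575 probes on array 1 (horizontal) and array 2 (vertical), coloured by spot brightness; dotted lines mark 2-fold and circles mark the 14 named genes past 2-fold with opposite signs. Of the 2258 probes in the dimmest of 10 groups 1967 lie below 0 on both arrays, as do the 228 control-like spots by their definition; 109 probes lie past 2-fold at the lower right and 35 at the upper left.

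**Figure D2:**
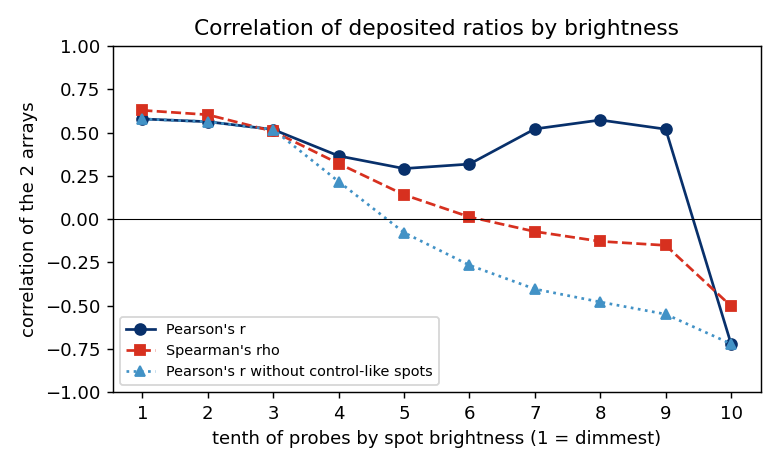
Pearson's r, with and without the control-like spots, and Spearman's rho of the deposited ratios of the 2 arrays (vertical) in 10 equal groups of probes from the dimmest to the brightest (horizontal). Pearson's r over all spots is 0.58 in the dimmest group, above 0 up to the ninth and −0.72 in the brightest; without control-like spots it is below 0 from the fifth.

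The second comparison asked which transcripts differed between exposed and unexposed seedlings. Read as deposited, 0 probes were at least 2-fold higher on both arrays and 1719 were at least 2-fold lower on both, where 0.251 and 325 would be expected of independent arrays. Of these 1719, 1344 lay in the dimmest of 4 brightness groups and 228 were control-like spots. The named genes among them with the lowest plain means were HKT1;5 at −2.67, AMT2-2 at −2.49, BURP10 at −2.003, OSH1 at −1.99, RDR4 at −1.97, DI19 at −1.95, GDH3 at −1.93, YSL4 at −1.93, EXPB8 at −1.90, CIPK10 at −1.85, and GSTZ5 and STR20 at −1.82 each. All 12 had a brightness of at most 3.84, below the 5.47 of the median gene.

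With array 2 turned, 109 probes were on the array 1 side and 35 on the array 2 side, where 15.7 and 5.19 would be expected of independent arrays. By the mean of the probes of each gene, from features with 1 gene, 79 and 26 genes were on these sides, of which 10 and 4 had a name. Over the 22347 probes without control-like spots, the spread of the plain mean after centring was 0.15 (scaled median absolute deviation) in the brightest of the 4 groups and 0.47 in the dimmest. It measures technical error only if the columns are 1 dye over the other. In the brightest group 122 probes had a centred swap mean of 1 or more in size, against 7 with a centred plain mean of that size.

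Jasmonate signalling had a median swap mean above that of most random lists. Its 20 measured genes had a median of 0.11, or −0.11 with the sign turned, at percentile 98.3 of random lists. The list was at percentile 99.7 on array 1 alone and 97.1 on array 2 alone, inside the central 95% there. Of these genes, 2 were on the array 1 side, 1, JAZ5, was at least 2-fold lower on both arrays, and 16 lay above the median of all genes. JAZ8, of the JAZ family of repressors of jasmonate responses, had a log2 ratio of 1.82 on array 1 and −2.32 on array 2, a swap mean of 2.07. JAZ7 followed with 1.03 and −1.70, a swap mean of 1.37, and JAZ11 with a swap mean of 0.92 did not pass 2-fold on array 1. Of the 18 jasmonate biosynthesis genes none was on either side and AOS3 was at least 2-fold lower on both arrays; their median of 0.09 was at percentile 95.2. AOS4, an allene oxide synthase of that pathway, had 0.98 and −1.41 and passed only after centring. LOX1.1 had a swap mean of 0.71, on a dim spot, and LOX5 one of 0.54. Both came in by symbol alone, so the list name need not hold for them.

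Phenylpropanoid and flavonoid enzymes, which make lignin precursors and phenolic compounds, had a median swap mean of 0.17 over 30 genes, or −0.17 turned, at percentile 99.99, and at 94.3 on array 1 alone. The coenzyme A ligase 4CL3 was the 1 member on the array 1 side, with 1.09 and −1.21, and CAD7 and LAC15 were at least 2-fold lower on both arrays. The methyltransferase ROMT-15 had 1.65 and −0.73, and the alcohol dehydrogenase family member CAD6 had 0.55 and −1.38. The 6 glutathione S-transferases, which conjugate glutathione to reactive compounds, had a median of 0.34, or −0.34 turned, at percentile 99.8, with GSTU6 at 0.90, a mean of 3 probes that disagreed in sign, GST-II at 0.78 and GST-I at 0.59; none was on either side, and GSTZ5 was at least 2-fold lower on both arrays. It was the 1 list of the 9 outside the central 95% of random lists that stayed there, on the same side, with each array alone. Percentiles of an array alone, here and for the other lists, were not matched on brightness. The centred plain mean rose with brightness (rho 0.73, without control-like spots). On an array alone such a trend can move a bright list up on array 1 and down on array 2 turned. A dim list can move the other way. The 55 auxin response genes had a median of 0.10 at percentile 99.8, and 89.9 on array 1 alone, led by GH3.9 with 0.69 and IAA2 with 0.65. The 64 expansins and cell wall enzymes had a median of 0.08 at percentile 99.4, but 86.8 on array 1 alone and 95.3 on array 2 alone, led by the cellulose synthase CESA4 with 0.87, EXPB2 with 0.86 and CESA3 with 0.73. In neither of these last lists was a gene on either side, and in each 3 were at least 2-fold lower on both arrays.

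Cytosolic ribosomal proteins had the lowest median swap mean of the 30 lists, with no gene on either side. Their 19 genes had a median swap mean of −0.28, or 0.28 turned, below all 10000 random lists but at percentile 6.10 on array 1 alone, and 2 lay above the median of all genes. RPL18, also named CL18, had −0.50, RPL30 −0.49 and RPL11 −0.47. As symbols alone set the ribosomal list, its name need not hold for every member, RPL18 included. The 6 genes of the Calvin cycle and Rubisco list had a median of −0.25 at percentile 0.16, and 2.79 on array 1 alone. The FBPase gene LOC4325071, also named CFBP1 and MOC2, had −0.68, the Rubisco activase rca −0.52 and RPE −0.45. Symbols alone set this list, which took in the glycolate oxidase gene GLO1 at −0.06, a mean of 2 probes that disagreed in sign. The list name need not hold for every member, LOC4325071 included. The other FBPase gene, LOC4332364, on a dim spot, had −1 and −1.58, a swap mean of 0.29, and was the 1 member at least 2-fold lower on both arrays. The 61 genes of histones and the cell cycle had a median of −0.08 at percentile 0.04, and 2.53 on array 2 alone, and 3 were at least 2-fold lower on both arrays. The 18 actin, tubulin, ubiquitin and elongation factor genes, often used as reference genes, had a median of −0.10 at percentile 0.79, which was 7.60 among lists matched on brightness and 98.0 on array 1 alone, the opposite end; their members went both ways, with ACT7 at 0.57 and ACT3 at −0.46. The other 8 of these 9 lists stayed outside the central 95% with matching. Chance would put 1.5 of the 30 lists outside it if genes varied independently. Genes of a list may vary together within 1 RNA sample, so more lists could fall outside without any effect of the treatment. Photosystem and light-harvesting proteins, the brightest list with a median brightness of 12.1, had a median of −0.03 at percentile 23.8, 96.1 on array 1 alone and 0.06 on array 2 alone, with CAB2R at 0.69 and petC at −0.65.

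By the plain mean, as planned, 4 of the 30 lists lay outside the central 95%, all above it, where the median of all genes was −0.26. Photosystem and light-harvesting proteins had a median of 0.02 at percentile 99.97, chlorophyll and haem synthesis −0.07 at 99.7, the actin, tubulin, ubiquitin and elongation factor list −0.09 at 99.7, and protease inhibitors and antimicrobial peptides −0.04 at 99.2. Among lists matched on brightness these lay at percentiles 91.6, 74.1, 35.9 and 96.3, inside the central 95%. With matching 1 other list lay outside it, below: cytosolic ribosomal proteins, with a median of −0.17 at percentile 1.47. Unmatched, that list was at percentile 91.7.

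**Figure D3:**
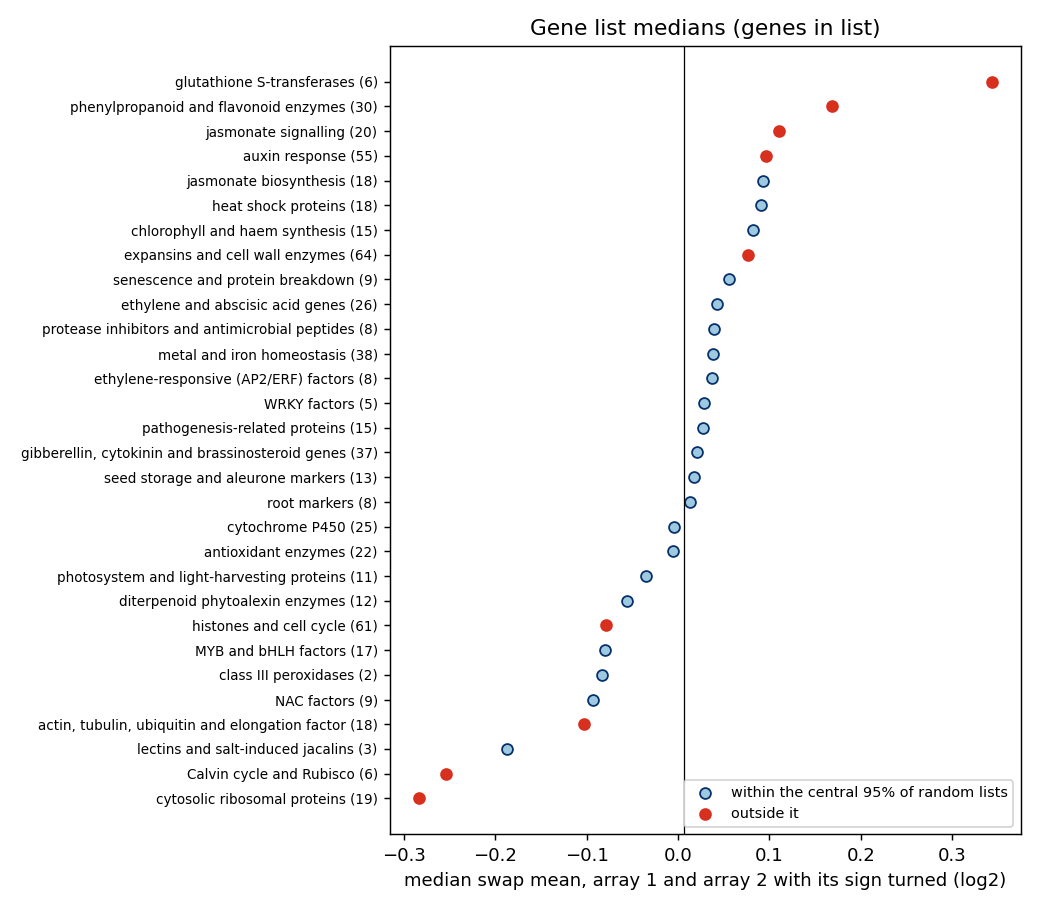
Median swap mean (log2, horizontal) of the genes in each of the 30 lists, with the number of genes in brackets; the vertical line is the median of all genes, and filled red points lie outside the central 95% of 10000 random lists of the same size. Glutathione S-transferases are highest at 0.34 and cytosolic ribosomal proteins lowest at −0.28.

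The largest named gene on the array 1 side was CRSH2, which belongs to the family of enzymes that make and break down the nucleotide ppGpp, with 2.95 on array 1 and −2.83 on array 2, a size of 7.40-fold. It was followed by the beta-glucosidase BGLU30 at 5.00-fold, JAZ8 at 4.21-fold and the catalase CAT-A, which breaks down hydrogen peroxide, at 3.38-fold. The mannose-binding lectin salT had 2.44-fold, the acyltransferase AT4 2.31-fold, the glycolate oxidase family member GLO4 2.26-fold and the chitinase Cht4, of the pathogenesis-related list, 2.08-fold. On the array 2 side stood MADS56, a MADS-box factor, at 3.83-fold on a dim spot, PPDK2 at 2.82-fold, OsNrx1-1 at 2.18-fold and FOR1 at 2.12-fold. FOR1 was also on a dim spot, with a log2 ratio of −1 on array 1, at the threshold. After centring, 8 of these 14 genes still passed 2-fold on both arrays, and AT4, 4CL3, Cht4, GLO4, OsNrx1-1 and FOR1 did not. Among genes with a locus number only, LOC4347708 had 4.53 and −4.12, a size of 20.05-fold, and LOC4347709 had 3.31 and −3.43.

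Other lists held single genes of some size while their medians lay within the central 95%. PORA, a light-dependent enzyme of chlorophyll synthesis, had 0.97 and −1.13 with a swap mean of 1.05, and the median of its 15-gene list was 0.08 at percentile 90.9. That list, with a median brightness of 7.83, was at percentile 99.45 on array 1 alone and 4.21 on array 2 alone. These lie towards opposite ends only with array 2 turned. The type A response regulators RR9 and RR6, of cytokinin signalling, had swap means of −0.93 and −0.90, and the gibberellin synthesis gene KAO −0.81. NAS2, a nicotianamine synthase of iron uptake, had 1.004, the cytochrome CYP71P1 1.20, the chlorophyll breakdown gene SGR 0.81 and the factor BHLH063 0.71. Root markers had a median of 0.01 over 8 genes at percentile 53.1, and seed storage and aleurone markers 0.02 over 13 genes at percentile 56.6. The seed storage and aleurone list was at percentile 0.16 on array 1 alone and 91.3 on array 2 alone with its sign turned. As deposited its medians were −0.67 and −0.49, so the arrays went the same way before turning. Its median brightness was 3.70, and the trend of the plain mean with brightness can give such a split.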

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

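The alternatives on the sides, on the swap mean, on control-like spots, on the brightest of 10 groups, on matching, on names by spot number and on turning array 2 for lists and named genes were chosen after seeing the data, and the cause of a change was not tested unless named. The count of probes at least 2-fold higher on both arrays was 0 under centring, scaling, other thresholds, genes and brightness filters, 1 with the mean alone, 46 to 123 with an array alone, and 109 with array 2 turned. The count lower on both, 1719, was 771 centred, 746 scaled, 3736 at 1.5-fold, 475 at 3-fold, 609 as genes, 375 without the dimmest spots, 35 with array 2 turned, and 2545 to 2882 with an array alone. On the array 1 side 109 became 287 at 1.5-fold, 35 at 3-fold, 186 by the swap mean alone, and 123 to 2882 with an array alone; centring gave 117. On the array 2 side 35 became 119, 8, 64 and 46 to 2545, and centring gave 32. The correlation of 0.54 was 0.42 without the 1% most extreme probes, 0.24 over genes, 0.40 without control-like spots and −0.72 in the brightest of 10 groups, where it turned round. Of the 30 list medians of the plain mean, 4 lay outside the central 95%, against 1 matched on brightness, 9 with array 2 turned, and 8 to 9 with an array alone. By the swap mean 9 lay outside, 8 to 9 with an array alone, where 3 of the 9 on array 1 and 6 on array 2 stayed outside at the same end, and 4 with names by spot number, where 0 of the 9 did. Lists outside the central 95% that crossed the middle of random lists were, for the plain mean, the actin, tubulin, ubiquitin and elongation factor list at −0.0859 matched on brightness, this list at −0.103 and the photosystem list at −0.0349 with array 2 turned, and with names by spot number this list at −0.398 and protease inhibitors at −0.638. For the swap mean they were the actin list at −0.0803 for array 1 alone, with −0.0496 for array 2 alone, and with names by spot number jasmonate signalling at −0.00488, phenylpropanoid enzymes at −0.0108, the Calvin cycle at 0.128, ribosomal proteins at 0.0577 and auxin response at −0.0273. The 79 named genes of the plain mean were 22 centred, 20 scaled, 14 with array 2 turned and 152 to 203 with an array alone; the 14 by side were 14 centred or scaled, of which 8 were the same genes, and 152 to 203 with an array alone. The plain mean spread more at dim spots, 0.47 against 0.15 at bright ones. No paired analysis was possible because the arrays are 1 replicate.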

Other observations

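The tests of a channel offset, of treated over control on both arrays, of dye effects without control-like spots, of the other probe of a gene, and of neighbours far apart on the array were chosen only after the results were seen. The loci LOC4347708 and LOC4347709 led the array 1 side, 3 places apart in gene order on 1 chromosome, a pair singled out after its values were seen. Heat shock proteins had a median swap mean of 0.09 over 18 genes at percentile 94.8, ethylene and abscisic acid genes 0.04 over 26 at percentile 81.2, and MYB and bHLH factors −0.08 over 17 at percentile 3.51. Diterpenoid phytoalexin enzymes had −0.06 over 12 genes at percentile 13.0. Of the 22 antioxidant enzymes only CAT-A passed 2-fold on both arrays, and the median of that list was −0.01. The lists not yet named ranged from percentile 4.77, for lectins and salt-induced jacalins, to 82.8, for metal and iron homeostasis.

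Ratios of 1/2 or less on both arrays were the main feature of the values as deposited. Control spots alone do not account for the positive correlation, since r was 0.40 without the 228 control-like spots. A fall of RNA in exposed seedlings, with both columns as treated over control, stays open: r was −0.72 in the brightest of 10 groups, but dye effects of bright probes could give that too. At 81 of the 1491 probes lower on both arrays a bright second probe of the same gene had a median centred plain mean of 0.18, against 0.17 for all bright probes, but brightness, which chose these probes, itself went with the plain mean (rho 0.73), so this decides nothing. A channel offset at dim spots may explain the pattern. In the dimmest of 4 groups 23.8% of probes were at least 2-fold lower on both arrays, and 0.0902% in the brightest. An offset tied to a dye would give the same sign on both arrays only if the columns are 1 dye over the other. What makes the offset stays open, since background correction is not given in the sources used here.

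The array 1 side held more probes than the array 2 side, and an offset of the column medians is argued against by 117 and 32 probes after centring. Dye effects give the same sign on both arrays if the columns are dye over dye and opposite signs if treated over control, so counts of same-sign probes above the median brightness, 211, of which 201 were control-like, against 108 with opposite signs, and 10 against 108 without these, decide nothing while the numerator is not stated. Over all 1690 pairs of probes for 1 gene the correlation of the swap mean was 0.30, which does not bear on why 1 side holds more. In 16 genes with exactly 1 of 2 probes on a side the other probe had a median centred swap mean, signed by that side, of 0.085, far below the first, and 0.21 when 3 genes with both probes on a side entered 2 times each; the other probes were chosen for missing the threshold, so this decides nothing. Dye effects, of single probes or shared by those of a gene, and an effect of jasmonic acid as a hypothesis stay open, with 1 replicate and no stated numerator.

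Jasmonate signalling genes had a raised median swap mean, with 2 of 20 on the array 1 side. A trend of the swap mean with brightness is argued against by percentile 98.2 among lists matched on brightness. Placement of names by chance is argued against by 1 of the 97 other grid rearrangements, which gave a list median at least as far from that of all genes; the value was 0.10 on the chosen grid and 0.11 on that other one. The other rearrangements give the names to arbitrary spots. This count therefore resembles the draw of random lists and is no separate evidence for the grid. If the array 1 side is the treated RNA, these genes may be higher after exposure, but the files do not state the numerator and the list was not used to set it.

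A hypothesis that genes next to each other in the genome go together was raised by the leading pair of loci, which lie 3 places apart and so are not among the neighbours tested. Over 7825 pairs of neighbouring genes the Spearman correlation of the swap mean was 0.036, and 4 of 1000 shuffles gave a value at least as large in size. It was 0.023 over the 2061 pairs with both genes above the median brightness, and 0 pairs passed 2-fold on the same side, as in the median shuffle. A local bias of the array may give such a value: spots next to each other reached 0.14, at least the value of neighbouring genes, which is what had been set down for that bias before the result was seen. A test added later left out the 92 of 6116 pairs of genes with 1 probe each whose spots lay within 10 lines and spots of each other; the other 6024 gave 0.036, with an SD of 0.013 over shuffles, which argues against a bias of that reach only and leaves a longer one open.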
